A study of Homo sapiens with 20 samples.

How the data were processed

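SRF occupancy of promoters was measured by ChIP-chip on Agilent 2-colour proximal promoter arrays. Per the labels, ChIP DNA (antibody sc-335) was labelled with the red dye and mock immunoprecipitation DNA with the green dye. The 20 arrays held 10 replicates of 4 groups on 2 array designs. The label of a serum array gave no replicate number or design, and a BE(2)-C array was labelled replicate a. Both were taken here as replicate 1, and fits with the replicate block left them out. No arrays with swapped dyes were present, so dye bias was not removed. The deposited scanner files hold the red and green signal as intensity, per the file headers, made by Agilent Feature Extraction 8.5.1.1 (the 6 arrays of Jurkat with serum) or 8.5.3.1 (the other arrays). The scanner software had subtracted background, removed spatial trends and applied a linear dye normalisation. The deposited series matrix gives the log10 ratio of red over green, per the labels. It equalled the scanner's log10 ratio to rounding on the arrays of the other groups and differed from it on the serum arrays, and how those values were made is not given in the sources used here. The crosslinking, the amount of chromatin and the genome build are not given in the sources used here.

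The value of a probe was the log2 ratio of the processed red over green signal, centred on the array's median, after probes the scanner software had marked as outliers were removed. The designs held 41558 and 41554 probes. Probes less than 1000 bp apart on a design formed a region, and a region's value was the mean of its probes. Of 18056 regions, 60 on chromosome Y or at XIST were left out, 1205 with 1 probe were tested separately, and 16791 with at least 2 probes were analysed (8463 and 8328 per design), with a median of 5 probes and 1110 bp. Gene symbols came from the array files, and 2285 regions had several genes and 228 none. The median absolute deviation of the log2 ratio per array was 0.376 to 0.768 in Jurkat with serum, 0.339 to 0.446 in untreated Jurkat, 0.282 to 0.707 in BE(2)-C and 0.260 to 0.336 in CRL-1999. Mock signals stood well above background for 69.8% to 94.1%, 83.2% to 90.6%, 84.6% to 92.7% and 82.3% to 91.3% of probes in those groups.

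Each design was fitted in limma 3.58.1 (R 4.3.3) with a mean per group, all groups sharing the estimate of spread. Enrichment was tested against a minimum of 1.5-fold (treat), and group differences against 0 with the moderated t-test. P-values of both designs were adjusted together with the Benjamini-Hochberg method, at a threshold of 0.05. A region was called enriched when it passed above mock. The comparisons were Jurkat with serum against untreated Jurkat, BE(2)-C and CRL-1999 each against untreated Jurkat, and BE(2)-C against CRL-1999. Gene lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, and members were also adjusted over the list alone. The 12 lists were immediate early genes, actin cytoskeleton genes, smooth muscle contractile genes, striated muscle genes, SRF and its cofactors, T cell genes, sympathetic neuroblast genes, fibroblast genes, endothelial genes, ribosomal protein genes, replication-dependent histone genes and olfactory receptor genes. Regions, groups, comparisons, lists, thresholds, the naming rule and the first alternatives were fixed before the data were examined.

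Genes were named by a rule. Per group these were the 10 enriched regions with the highest mean that were above 0 in every replicate and had a gene symbol. Per comparison they were the 10 largest differences each way past the threshold, enriched in the higher group and without overlap of replicates. All list members called enriched (the 6 highest if more) and all regions enriched in all 3 cell types were added, with SRF, FOS, EGR1, ACTB and ACTA2 always named. Genes outside this rule are said to have been chosen after their values were seen. Shared calls against the same untreated arrays were counted in 100 simulations of unchanged groups.

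In simulated data, 100 regions each were raised by log2 1.5 and 2.5. All other regions were noise around 0 with their measured spread, independent between arrays. The test recovered 64% and 96% of enriched regions in Jurkat with serum and 41% and 88% in untreated Jurkat. It recovered 73% and 97% in BE(2)-C and 51% and 94% in CRL-1999. The 0 false calls follow largely from the minimum fold. No shared effects of scan day, probe length or dye were simulated, so these rates need not hold for the measured arrays. For the comparisons it recovered 65% and 92% (serum against untreated Jurkat), 66% and 91% (BE(2)-C against untreated Jurkat), 58% and 86% (CRL-1999 against untreated Jurkat) and 64% and 88% (BE(2)-C against CRL-1999), with 13, 7, 5 and 9 false calls.

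The alternatives were normexp background correction (offset 50), loess within arrays (span 0.3), arrays scaled to one median absolute deviation, the authors' series matrix values, dim probes left out, at least 3 probes, the best neighbouring pair of probes, the median over probes, a variance trend with robust fitting, array weights, replicate number as a block, scan day as a random block, minimum folds of 1.25 and 2, only the 2 groups compared, other Jurkat comparators, adjustment over enriched regions alone, and each replicate left out. When a left-out replicate leaves 1 sample in a group, that sample is assumed to vary like the other groups. Chosen after the data were seen were a probe length correction (loess, span 0.75), that correction with the replicate block, the fit without the Jurkat serum group, and the fits without the CRL-1999 arrays of scan day 5 or 6. No genome sequence was used here, so tests of CArG motifs, a correction for GC content and the replicate block with GC content were not run. Random regroupings were not run, since no comparison had 3 or more replicates in both groups. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.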

Results

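Serum response factor (SRF) is a MADS-box transcription factor that binds CArG boxes in the promoters of growth-response and muscle genes. Its promoter occupancy was measured by chromatin immunoprecipitation on proximal promoter arrays (ChIP-chip) in 3 human cell types. Jurkat is a T cell leukaemia line, BE(2)-C a neuroblastoma line and CRL-1999 a smooth muscle cell culture. Jurkat cells were profiled untreated (2 replicates) and after 24 h of serum (3 replicates), BE(2)-C in 3 replicates and CRL-1999 in 2 replicates. Each replicate was hybridised to 2 array designs, 20 arrays in all, and each promoter region lay on 1 design, so that n below is the number of replicates. The measurement was the log2 ratio of SRF ChIP over mock immunoprecipitation from the same cell type, centred on each array's median. The mock was therefore the background in every value. ChIP signals stood well above background for 77.5% to 85.1% of probes in untreated Jurkat, 63.0% to 75.5% in BE(2)-C, 82.1% to 90.7% in CRL-1999 and 52.7% to 94.2% in Jurkat with serum. The number of arrays limited the precision of every value. The labels did not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

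The first question of the design was which promoters SRF occupied in each cell type. The promoters of EGR1 and EGR2, immediate early genes for zinc finger transcription factors, were enriched in all 4 groups. At EGR1 (chromosome 5, 137828214 to 137829672, 4 promoter probes and 1 inside the gene) ChIP exceeded mock 9.56-fold in untreated Jurkat (log2 3.26 ± 0.16, SD, n = 2) and 9.95-fold in BE(2)-C (log2 3.31 ± 0.12, SD, n = 3). The EGR1 ratio was 6.42-fold in Jurkat with serum (log2 2.68 ± 0.19, SD, n = 3) and 4.16-fold in CRL-1999 (log2 2.05 ± 0.53, SD, n = 2). EGR2 (chromosome 10, 64245728 to 64247068, 4 promoter probes and 3 inside the gene) reached 12.3-fold in untreated Jurkat (log2 3.62 ± 0.43, SD, n = 2), 5.62-fold in BE(2)-C (log2 2.49 ± 0.56, SD, n = 3) and 4.89-fold in CRL-1999 (log2 2.29 ± 0.34, SD, n = 2). The zinc finger gene ZNF548 (chromosome 19, 62592322 to 62593114) and a chromosome 17 region for which no gene symbol was given (40750377 to 40751128, 3 probes) were the other promoters enriched in all 3 cell types. The chromosome 17 region was at log2 3.62 ± 0.04 (SD, n = 2) in untreated Jurkat, 3.49 ± 0.54 (SD, n = 3) in BE(2)-C and 2.63 ± 0.26 (SD, n = 2) in CRL-1999. The genome build of these coordinates was not given in the sources used here.

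Of 16791 promoter regions tested with limma against a minimum of 1.5-fold, 58 were enriched in untreated Jurkat, 38 in Jurkat with serum, 17 in BE(2)-C and 4 in CRL-1999. Below mock, the same test called 1 region in untreated Jurkat, 1 in BE(2)-C and 0 in the other groups. At an unadjusted p under 0.05, regions below mock numbered 73 in untreated Jurkat, 27 in Jurkat with serum, 19 in BE(2)-C and 16 in CRL-1999. Regions above mock numbered 221, 276, 194 and 86 in the same order. In total 71 regions were enriched in at least 1 group, and 39 of them in exactly 1. These counts moved when single replicates were left out and when the scan day was a random block. Untreated Jurkat and BE(2)-C were each scanned on 1 day, so the block cannot show that their counts depended on day. It carries over to them the spread between days, seen only within Jurkat with serum and CRL-1999. A fit with a replicate left out also has fewer samples. Leaving out 1 replicate at a time gave 12 to 75 enriched regions in untreated Jurkat (12 without its replicate 2, 19 without its replicate 1), 21 to 80 with serum (80 without serum replicate 3, 21 without serum replicate 2), 3 to 19 in BE(2)-C (3 without replicate 1 or 3) and 0 to 8 in CRL-1999, and with the scan day as a random block the counts were 15, 22, 2 and 0.

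The SRF promoter itself was among the enriched regions in both Jurkat groups and in BE(2)-C. At SRF (chromosome 6, 43246193 to 43246881, 3 promoter probes) the ratio was 5.70-fold in untreated Jurkat (log2 2.51 ± 0.15, SD, n = 2, adjusted p = 0.00021), 2.92-fold with serum (log2 1.54 ± 0.23, SD, n = 3, adjusted p = 0.0137) and 3.75-fold in BE(2)-C (log2 1.91 ± 0.15, SD, n = 3, adjusted p = 0.00216). In CRL-1999 SRF lay at 3.32-fold (log2 1.73 ± 0.03, SD, n = 2), short of the threshold (adjusted p = 0.058). FOS and FOSB, which encode AP-1 subunits, and MCL1, an anti-apoptotic BCL2 family gene, were enriched in untreated Jurkat at log2 2.11 ± 0.27, 2.46 ± 0.50 and 2.67 ± 0.78 (SD, n = 2) and in BE(2)-C at 2.27 ± 0.33, 1.95 ± 0.21 and 2.03 ± 0.62 (SD, n = 3). The region shared by CCNB1IP1 and PARP2 reached 10.5-fold in untreated Jurkat and 3.89-fold in BE(2)-C, and FAM32A 5.56-fold and 3.77-fold. In CRL-1999 the same promoters were measured at log2 1.05 (FOS), 0.98 (FOSB), 1.11 (MCL1), 1.46 (CCNB1IP1 and PARP2) and 1.95 (FAM32A), none of them past the threshold. ACTB, the cytoplasmic beta-actin gene, lay between 1.34-fold (CRL-1999) and 1.93-fold (Jurkat with serum) and was not enriched in any group.

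**Figure D1:**
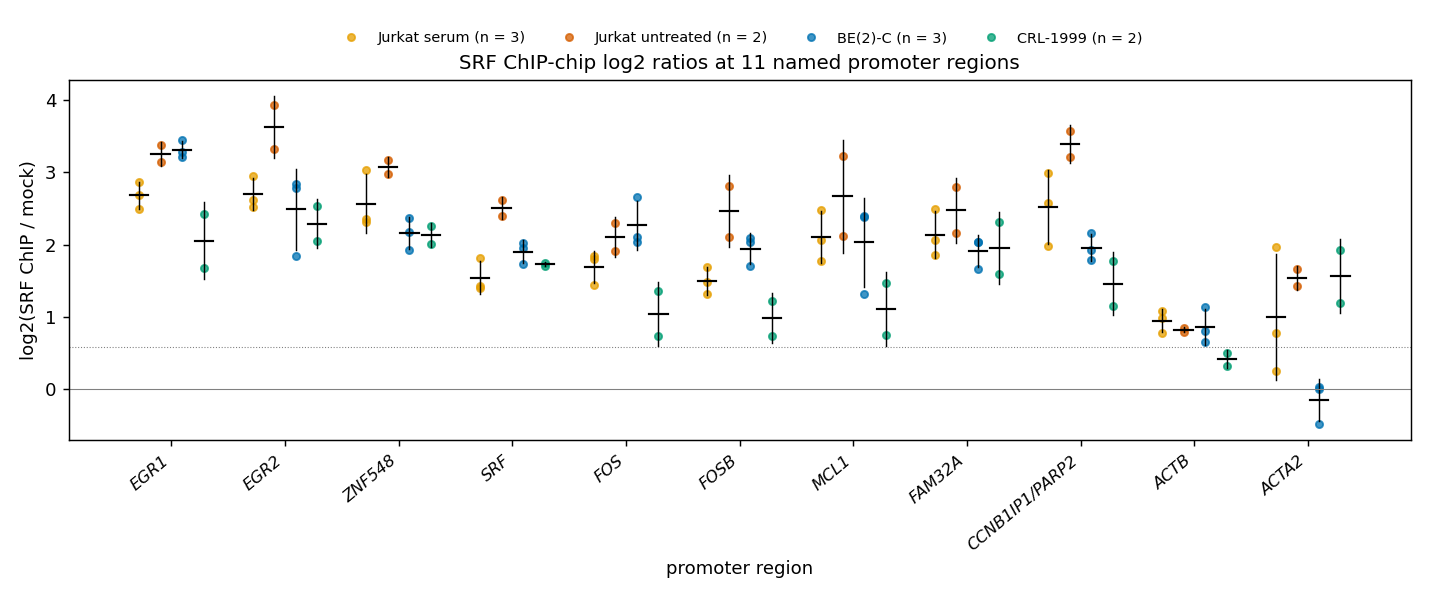
SRF ChIP over mock (log2 ratio, vertical axis) at 11 promoter regions (horizontal axis) in the 4 groups. Points are replicates, horizontal bars means, vertical bars the SD, and the dotted line marks the minimum of 1.5-fold. EGR1 lay at 2.05 or more in each group mean, and ACTB at 0.42 to 0.95.

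Further promoters had high ratios. In untreated Jurkat the 10 highest named regions included CD48, a surface receptor of lymphocytes (8.04-fold), GBP2, an interferon-inducible GTPase (7.67-fold), CEACAM21 (7.64-fold), LCP1, the leukocyte actin-bundling protein L-plastin (7.45-fold), and PLAC8 (6.64-fold). EIF2B2, which encodes a subunit of a translation initiation factor, was among the 10 highest with serum (4.56-fold) and was also enriched in untreated Jurkat (3.07-fold). In BE(2)-C the 10 highest included NR2F1, an orphan nuclear receptor gene (5.05-fold), DUSP5, a phosphatase gene of the ERK pathway (4.86-fold), and TUFT1 (3.79-fold). NR2F1 and TUFT1 did not pass as different from untreated Jurkat (differences 0.75, SE 0.29, adjusted p = 0.451 and 0.06, SE 0.35, adjusted p = 0.979), and TUFT1 was measured at 4.54-fold in CRL-1999 and 3.64-fold in untreated Jurkat.

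The gene lists fixed in advance gave the clearest enrichment for the 20 immediate early gene promoters. Of these, 5 were enriched in untreated Jurkat, 6 in BE(2)-C, 4 in Jurkat with serum and 2 in CRL-1999, and 8, 9, 7 and 2 when adjusted over the list alone (with 1 below mock in Jurkat with serum). The list lay above other promoters in untreated Jurkat (median log2 0.97, camera adjusted p = 2.36e-15, and adjusted p = 0.000365 with an estimated correlation), in BE(2)-C (median 0.54, adjusted p = 1.01e-11, and adjusted p = 0.00414 with an estimated correlation) and in CRL-1999 (median 0.55, adjusted p = 9.01e-18, and adjusted p = 8.26e-05 with an estimated correlation). With serum the median was 0.22 (mean 0.65), with adjusted p = 0.000628, and adjusted p = 0.288 with an estimated correlation. Of 32 actin cytoskeleton promoters, the regions of TADA3 and ARPC4 and of MUS81 and CFL1 were enriched in untreated Jurkat (log2 1.88 and 1.86) and VCL, the vinculin gene, in BE(2)-C (log2 1.67 ± 0.23, SD, n = 3), with 2 and 2 when adjusted over the list alone, and 1 with serum. In CRL-1999 none of the 32 was enriched over all regions (0, and 4 adjusted over the list alone), while the list's mean of 0.38 passed the set test (adjusted p = 4.54e-11, and adjusted p = 0.00334 with an estimated correlation).

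As a set, the 22 smooth muscle contractile promoters lay above other promoters in CRL-1999, the smooth muscle cells, with a mean of 0.40 carried by part of the members (median 0.23, SD 0.717, 14 of 22 above 0, adjusted p = 1.33e-07, and adjusted p = 0.00186 with an estimated correlation). None of them was enriched over all regions in any group (0 of 22), and when adjusted over the list alone 4 were in CRL-1999, 2 in Jurkat with serum and 0 in the other groups. ACTA2, smooth muscle alpha-actin, was measured at log2 1.56 ± 0.51 (SD, n = 2) in CRL-1999, 1.54 ± 0.17 (SD, n = 2) in untreated Jurkat and -0.15 ± 0.29 (SD, n = 3) in BE(2)-C. TAGLN, the actin-binding protein SM22, and CALD1, caldesmon, named here after their values were seen, lay at 1.73 ± 0.54 and 1.74 ± 0.43 (SD, n = 2) in CRL-1999, with adjusted p = 0.108 and 0.317. Each has a second region, which lay at 0.08 (TAGLN) and 0.12 (CALD1) in CRL-1999. In untreated Jurkat the first regions lay at -0.49 and 0.13, and in BE(2)-C at -0.24 and 0.38.

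Among the 12 promoters of SRF and its cofactors, SRF was the 1 enriched in untreated Jurkat, with serum and in BE(2)-C (1 in each of the 4 groups adjusted over the list alone, with CRL-1999 at 0 over all regions), and the list passed no set test with an estimated correlation (lowest adjusted p = 0.196). Of 24 T cell promoters, IL2RA, an interleukin 2 receptor chain, was enriched in untreated Jurkat (log2 2.06 ± 0.07, SD, n = 2), and adjusted over the list alone 1 was there and 1 with serum. The T cell list's mean with serum was 0.50 (adjusted p = 5.68e-05, and adjusted p = 0.0784 with an estimated correlation). Of 88 ribosomal protein promoters, RPL24 (log2 2.14 ± 0.10, SD, n = 2) and RPL32 (2.01 ± 0.04, SD, n = 2) were enriched in untreated Jurkat and RPL24 with serum (1.67 ± 0.05, SD, n = 3), with 3 and 1 adjusted over the list alone. That list's mean in CRL-1999 was 0.26 (adjusted p = 5.64e-13, and adjusted p = 0.0851 with an estimated correlation). No promoter was enriched, nor any when adjusted over the list alone, among 26 striated muscle, 21 sympathetic neuroblast, 15 fibroblast, 12 endothelial, 40 histone and 285 olfactory receptor promoters (0 each). With an estimated correlation none of these 6 lists passed in any group, except that the endothelial promoters lay lower in untreated Jurkat (mean -0.29, adjusted p = 0.0279, and adjusted p = 0.047 with an estimated correlation). Mean, median and direction of the set test differed in sign in at least 1 group for the actin, smooth muscle, striated muscle, fibroblast and SRF cofactor lists, in no case where the list passed.

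The next question was how far 24 h of serum changed SRF occupancy in Jurkat cells. The immediate early promoters lay lower with serum as a set. Their mean difference was -0.46 on the log2 scale, 2 of 20 were above 0, and the set test gave adjusted p = 3.59e-08, and adjusted p = 0.0316 with an estimated correlation. The mean was -0.31 with loess within arrays, -0.35 after normexp correction and -0.68 after scaling. These settings do not correct for probe length, which serum replicate 2 followed (r 0.546 and 0.623). At the preset correlation the ribosomal protein, histone and actin cytoskeleton lists also lay lower (camera adjusted p = 8e-05, 0.000442 and 0.00201). Olfactory receptor, neuroblast and T cell lists lay higher (8.92e-08, 0.0039 and 0.0217). None of these passed with an estimated correlation (lowest adjusted p = 0.141). Single immediate early members fell short of the threshold. EGR1 differed by -0.58 (SE 0.28, adjusted p = 0.541), EGR2 by -0.93 (SE 0.34, adjusted p = 0.444), FOS by -0.41 (SE 0.29, adjusted p = 0.675) and FOSB by -0.96 (SE 0.28, adjusted p = 0.409). SRF differed by -0.97 (SE 0.25, adjusted p = 0.358), and CD48 by -0.10 (SE 0.26, adjusted p = 0.929).

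With limma, 0 of 16791 regions differed between serum-treated and untreated Jurkat, against 1207 higher and 415 lower at an unadjusted p under 0.05, and the lowest adjusted p was 0.114. Among the 66 regions enriched in either group the median difference was -0.55, 56 of 66 lay below 0, and 30 were enriched in both groups (0.131 for independent lists). Adjusted over those 66 alone, 4 were lower with serum, namely GABARAPL2, an autophagy gene (-1.51, SE 0.27, adjusted p = 0.00453), the region of IRF3 and BCL2L12 (SE 0.27, adjusted p = 0.00453), GBP2 (-1.40, SE 0.28) and SRF (-0.97, SE 0.25, adjusted p = 0.0315). IRF3 and BCL2L12 are named after their values were seen, and the 66 regions were selected on the same arrays, so this count is not independent evidence. The serum replicates agreed least with each other, with a median r of 0.150 across regions against 0.558 in untreated Jurkat and 0.260 between arrays of different groups, so that the serum mean stands for replicates that differ widely. Serum arrays were scanned on days 1 to 3 with Feature Extraction 8.5.1.1 and untreated arrays on day 4 with 8.5.3.1, so serum cannot be told apart from day and software version. Without serum replicate 3 the test called 86 regions (71 higher and 15 lower with serum), of which 23 were enriched in either group, 21 of them higher.

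The cell types were then compared, which asks where SRF occupancy depends on cell type. In BE(2)-C, 10 promoters lay lower and 1 higher than in untreated Jurkat. CD48 was enriched 8.04-fold in untreated Jurkat (log2 3.01 ± 0.07, SD, n = 2) and lay at 0.795-fold in BE(2)-C (log2 -0.33 ± 0.11, SD, n = 3), a difference of -3.34 (SE 0.26, adjusted p = 0.000112). LCP1 differed by -3.17 (SE 0.37, adjusted p = 0.0114) and CEACAM21 by -3.03 (SE 0.32, adjusted p = 0.0114). HCLS1, an actin regulator of blood cells, differed by -2.50 (SE 0.39, adjusted p = 0.0414). MICU2, a mitochondrial calcium uptake gene, LATS1, a Hippo pathway kinase gene, GBP2, PTER and UBXN10 also lay lower, between -2.33 and -1.94. MYO1E, an unconventional myosin gene (chromosome 15, 57452055 to 57453099), was the promoter higher in BE(2)-C, with log2 1.79 ± 0.19 (SD, n = 3) against -0.07 ± 0.31 (SD, n = 2) in untreated Jurkat (difference 1.86, SE 0.26, adjusted p = 0.0409). In each of the 11 regions the replicates of the groups did not overlap.

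EGR1, FOS and SRF differed from untreated Jurkat in BE(2)-C by 0.06 (SE 0.28, adjusted p = 0.971), 0.16 (SE 0.29, adjusted p = 0.900) and -0.60 (SE 0.25, adjusted p = 0.484). DUSP5 differed by 1.34 (SE 0.30, adjusted p = 0.234) and VCL by 0.99 (SE 0.25, adjusted p = 0.279). No gene list passed the set test of this contrast with an estimated correlation (lowest adjusted p = 0.335). The 11 calls came from 816 regions higher and 767 lower at an unadjusted p under 0.05, and among the 63 regions enriched in either group, adjusted over those alone, 4 were higher and 46 lower, a split that follows in part from the choice of 58 of them for high values in untreated Jurkat. With loess within arrays the calls were 5 higher and 17 lower, without the serum arrays in the fit 198 and 186. Of these last 384 calls, 61 were enriched in either group in that fit. They split into 7 higher and 54 lower, again in part through that choice. With the scan day as a random block 1 call was left and without 1 replicate of either group 1 or 2, while CD48 was called in 29 of 30 settings. BE(2)-C and untreated Jurkat arrays were each scanned on a single day of their own, so that day and cell type cannot be told apart in this contrast. Against Jurkat with serum, scanned on 3 other days, 15 promoters differed in BE(2)-C (3 higher, 12 lower), 7 of the 11 among them.

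**Figure D2:**
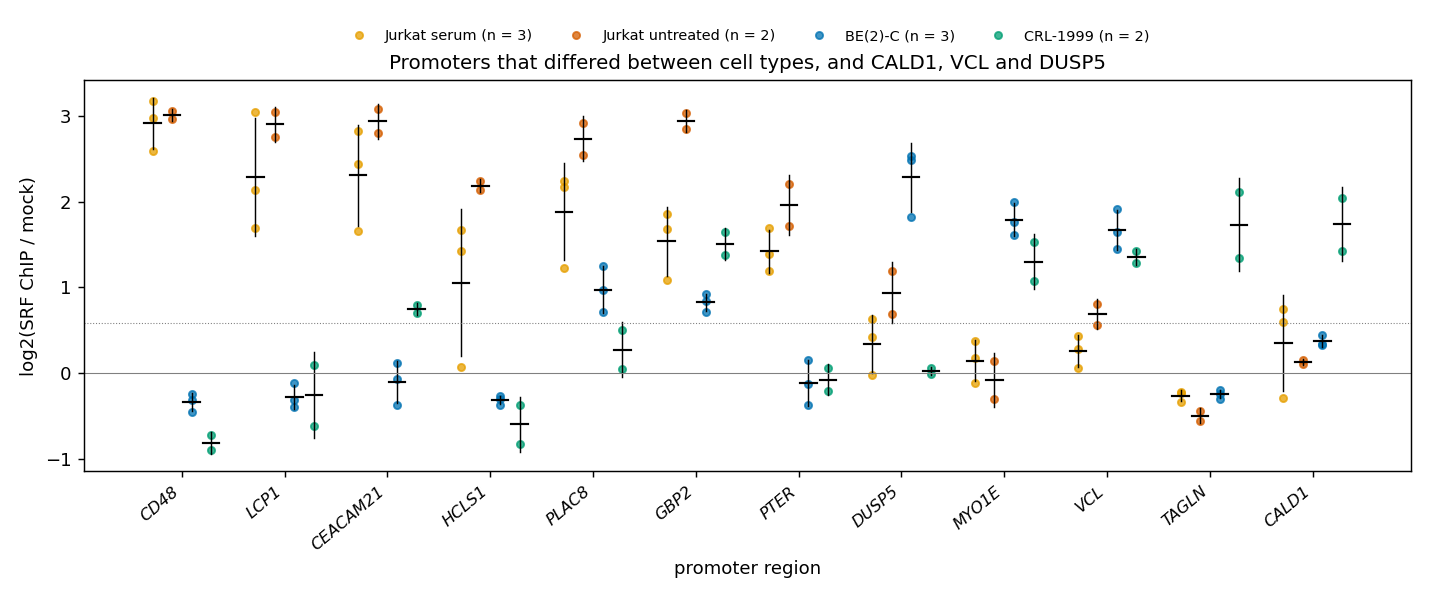
SRF ChIP over mock (log2 ratio, vertical axis) at promoters that differed between cell types, and at CALD1, VCL and DUSP5 (horizontal axis). Points are replicates, horizontal bars means, vertical bars the SD, and the dotted line marks the minimum of 1.5-fold. CD48 lay at 2.91 and 3.01 in the Jurkat groups and at -0.33 and -0.80 in BE(2)-C and CRL-1999.

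In CRL-1999, 6 promoters lay lower than in untreated Jurkat and 1 lay higher. CD48 differed by -3.81 (SE 0.28, adjusted p = 6.73e-05), LCP1 by -3.15 (SE 0.40, adjusted p = 0.0384) and HCLS1 by -2.78 (SE 0.43, adjusted p = 0.0449). PLAC8 differed by -2.45 (SE 0.37, adjusted p = 0.0429), where of its 4 probes 1 had a ChIP signal and 2 a mock signal not well above background on any CRL-1999 array, GABARAPL2 by -2.29 (SE 0.30, adjusted p = 0.0384) and PTER by -2.03 (SE 0.31, adjusted p = 0.0429). TAGLN (chromosome 11, 116574223 to 116575567, 4 promoter probes and 1 inside the gene) was the promoter higher in CRL-1999, by 2.22 (SE 0.27, adjusted p = 0.0384), and is named here after its values were seen, because it was not called enriched in CRL-1999. The replicates of the groups did not overlap at any of these 7 regions. The immediate early list had a mean of -0.42 (adjusted p = 9.17e-06, and adjusted p = 0.0889 with an estimated correlation), the smooth muscle list a mean of 0.30 (adjusted p = 0.00339, and adjusted p = 0.128 with an estimated correlation). EGR1 differed by -1.20 (SE 0.30, adjusted p = 0.541), EGR2 by -1.34 (SE 0.37, adjusted p = 0.799) and SRF by -0.78 (SE 0.27, adjusted p = 1.00).

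The 7 calls came from 372 regions higher and 344 lower at an unadjusted p under 0.05. All 58 regions enriched in either group lay below untreated Jurkat in CRL-1999 (median -1.05), and 47 of them passed when adjusted over those alone. They are the 58 chosen for high values in untreated Jurkat on the same arrays, so the one-sided drop follows in part from the choice. CRL-1999 arrays, too, were scanned on days of their own. The split of calls was 6 higher and 5 lower after normexp correction and 5 and 7 after scaling. Without the serum arrays in the fit it was 10 and 27. Of these last 37 calls, 25 were enriched in either group in that fit, 4 higher and 21 lower. With the scan day as a random block 1 call was left and without 1 replicate of either group 1 or 2, while CD48 was called in 30 of 30 settings. Of the lower promoters, 4 were shared with the BE(2)-C contrast, namely CD48, LCP1, HCLS1 and PTER. Apart from CD48 these calls depended on the setting. LCP1 kept its call in 22 of 30 settings in BE(2)-C and 15 of 30 in CRL-1999, and PTER in 21 and 14 of 30. HCLS1, a region of 2 probes, kept it in 12 and 13 of 29. Independent lists of these sizes would share 0.00357. Simulated unchanged groups against the same untreated arrays shared 0 calls (mean 0 and highest 0 of 100 simulations). Unchanged groups give hardly any calls, so this 0 cannot measure how shared controls raise the overlap of lists that hold real differences. The 2 untreated replicates are too few to be split between the comparisons, and part of the excess over independent lists may come from these shared controls.

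**Figure D3:**
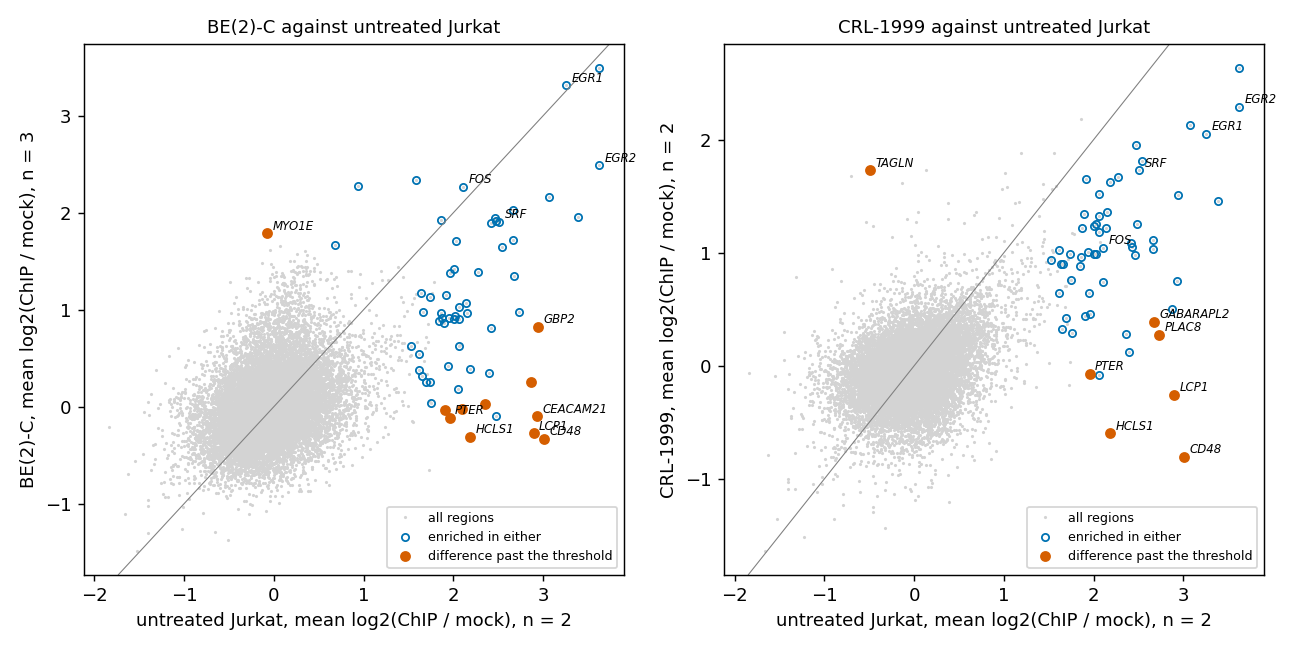
Mean log2 ratio of SRF ChIP over mock in untreated Jurkat (horizontal axes) against BE(2)-C and CRL-1999 (vertical axes) for all 16791 regions. Open circles mark regions enriched in either group, filled circles differences past the threshold (11 in BE(2)-C and 7 in CRL-1999), and the line equality. MYO1E and TAGLN lay above the line and the other filled circles below it.

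Between BE(2)-C and CRL-1999, 0 of 16791 regions differed with limma, against 957 higher and 381 lower in BE(2)-C at an unadjusted p under 0.05, with a lowest adjusted p of 0.101. DUSP5 came nearest to the threshold together with TAGLN, with log2 2.28 ± 0.40 (SD, n = 3) in BE(2)-C and 0.03 ± 0.04 (SD, n = 2) in CRL-1999 (difference 2.25, SE 0.30, adjusted p = 0.101). TAGLN lay lower in BE(2)-C by -1.97 (SE 0.25, adjusted p = 0.101) and ACTA2 by -1.71 (SE 0.42, adjusted p = 0.497). Adjusted over the 17 regions enriched in either group alone, which were selected on the same arrays, 4 were higher in BE(2)-C, namely DUSP5, EGR1 (1.26, SE 0.28), FOS (1.22, SE 0.29) and FOSB (0.96, SE 0.28). The smooth muscle list had a mean of -0.37 (adjusted p = 0.000201, and adjusted p = 0.0751 with an estimated correlation). The count of 0 depended on which arrays set the spread. Without the serum arrays in the fit 449 regions were called, with only these 2 groups 643 and with array weights 713. Of the 449, 406 were higher and 43 lower in BE(2)-C. Only 12 of them were enriched in either group in that fit (7 higher, 5 lower). The count and its direction also moved with the processing. Calls numbered 18 after normexp correction (0 higher, 18 lower) and 14 after scaling (5 higher, 9 lower).

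The overlap of the cell types was larger than for independent lists. Untreated Jurkat and BE(2)-C shared 12 enriched regions (0.0587 for independent lists), untreated Jurkat and CRL-1999 4 (0.0138) and BE(2)-C and CRL-1999 4 (0.00405). Regions below mock were meant as a gauge of shared probe bias. Only 1 was called in untreated Jurkat, 1 in BE(2)-C and 0 in CRL-1999. The 1 region was the same in untreated Jurkat and BE(2)-C, and so few regions cannot measure such bias. Over regions enriched in no group, the means of untreated Jurkat correlated with BE(2)-C (r 0.324) and with CRL-1999 (r 0.372). Between BE(2)-C and CRL-1999 r was 0.077. Such agreement, whatever its source, is not part of the numbers for independent lists. EGR1, EGR2, ZNF548 and the chromosome 17 region were the 4 enriched in all 3 cell types, and 8 further regions, SRF, FOS, FOSB and MCL1 among them, were enriched in untreated Jurkat and BE(2)-C and not called in CRL-1999. Of the 58 regions enriched in untreated Jurkat, 38 exceeded 1.5-fold in BE(2)-C (median log2 0.92) and 43 in CRL-1999 (median log2 1.00), against a median of 2.10 in untreated Jurkat itself. The overlap of all 3 was 0 with the scan day as a random block, with either CRL-1999 replicate left out and without untreated replicate 1 or 2, BE(2)-C replicate 1 or serum replicate 3, and it was 9 without the serum arrays.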

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

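Of the tests of the promoters lower in BE(2)-C or CRL-1999, those on T cell promoters, probe length and a weaker pull-down were chosen only after the result was seen, while the comparison against Jurkat with serum was planned.

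CD48, LCP1, HCLS1 and PTER were enriched in untreated Jurkat and lower in both BE(2)-C and CRL-1999, and 12 promoters were lower in either. LCP1, HCLS1 and PTER kept these calls in fewer settings than CD48. The median difference was -2.41 over the 10 promoters lower in BE(2)-C and -2.62 over the 6 lower in CRL-1999. The 24 T cell promoters had a median difference of 0.11 (SD 0.688) in BE(2)-C and -0.0457 (SD 0.576) in CRL-1999. Adjusted over the list alone, 3 were lower and 1 higher in BE(2)-C and 1 lower in CRL-1999. These values cannot decide on pull-down of promoters active in T cells without regard to SRF. The called promoters were chosen for large drops on the same arrays, and only 1 of the 24 was enriched in untreated Jurkat. A probe length trend is argued against by the 12 of 12 promoters that kept a call with the probe length correction. The 5 immediate early promoters enriched in untreated Jurkat had median differences of -0.52 (SD 0.531) in BE(2)-C and -1.34 (SD 0.201) in CRL-1999. They cannot decide on a weaker pull-down at all promoters, since the called promoters were chosen for large drops. In CRL-1999 all 58 regions enriched in untreated Jurkat lay lower (median -1.05), in part through their own choice for high values there. For CD48, an effect of the untreated arrays' day alone is hard to square with its 2.91 in Jurkat with serum, scanned on 3 other days. This does not extend to all 12 promoters, since GBP2 and GABARAPL2 lay lower with serum than untreated (-1.40 and -1.51). Against serum, 7 of 11 BE(2)-C calls and 1 of 7 CRL-1999 calls passed. Cell-type dependent SRF binding and an effect of the BE(2)-C or CRL-1999 days stay open as well.

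In BE(2)-C minus untreated Jurkat the values were -3.34 at CD48, -3.17 at LCP1, -3.03 at CEACAM21, -2.50 at HCLS1, -2.33 at MICU2, -2.12 at LATS1, -2.11 at GBP2, -2.07 at PTER, -1.94 at UBXN10 and 1.86 at MYO1E. In CRL-1999 minus untreated Jurkat they were -3.81 at CD48, -3.15 at LCP1, -2.78 at HCLS1, -2.45 at PLAC8, -2.29 at GABARAPL2, -2.03 at PTER and 2.22 at TAGLN.

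Regions with 1 probe were tested apart from the others, 1205 in all. KAT5, a histone acetyltransferase gene (chromosome 11, 65235976 to 65236021), was enriched in every group, at log2 2.56 in Jurkat with serum, 2.39 in untreated Jurkat, 2.47 in BE(2)-C and 2.49 in CRL-1999 (adjusted p = 0.00226, 0.00767, 0.00451 and 0.0217). The region of TBC1D10B and MYL11 was at 2.38 with serum, 2.91 in untreated Jurkat and 2.00 in BE(2)-C. SLC29A2 (1.92) and COG3 (2.32) passed with serum, CTNNBIP1 (2.60), HPF1 (2.61) and ZNF493 (2.08) in untreated Jurkat, and FGF1 (2.48) in CRL-1999.

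In array quality, replicate 1 of untreated Jurkat on array b had an SD of the log2 ratio of 0.842. Replicate 2 of BE(2)-C on array a had ChIP signals well above background at 63.0% of probes and a median raw ChIP signal of 92.3. These stood apart among 32 combinations of group and measure.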

How the results depend on the processing

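The probe length correction, its combination with the replicate block, the fit without the Jurkat serum group and the fits without the CRL-1999 arrays of scan day 5 or 6 were chosen only after the results were seen. No named difference or enrichment reversed its sign past the threshold in any setting. Counts below are promoters enriched or differing, against 38 in Jurkat serum, 58 in Jurkat untreated, 17 in BE(2)-C, 4 in CRL-1999, 11 in BE(2)-C minus Jurkat untreated, 7 in CRL-1999 minus Jurkat untreated, 0 in the other 2 comparisons and 4 enriched in all 3 cell types. Lists compare with 6 immediate early genes, 3 actin cytoskeleton genes, 0 smooth muscle contractile genes, 1 T cell gene, 2 ribosomal protein genes and 0 olfactory receptor genes. Replicate number showed no pairing of the samples (median r -0.06 over 21 same-number pairs, 0.01 over 40 others). This check cannot exclude pairing, since deviations in groups of 2 replicates mirror each other. In addition, the CRL-1999 replicate numbers were crossed between scan days 5 and 6 on the 2 designs. The causes of the moves below were not tested.

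With normexp background correction 8 promoters were enriched in Jurkat serum, 26 in Jurkat untreated, 2 in BE(2)-C, 15 in CRL-1999 and 2 in all 3 cell types, and 11 differed in CRL-1999 minus Jurkat untreated (6 higher, 5 lower) and 18 in BE(2)-C minus CRL-1999 (0 higher, 18 lower). Its lists gave 2 smooth muscle contractile, 0 T cell and 0 ribosomal protein genes, and it moved the median of Jurkat serum minus untreated over all regions from 0.10 to -0.06. With loess within array 60 were enriched in Jurkat serum and 2 in all 3 cell types, and 22 differed in BE(2)-C minus Jurkat untreated (5 higher, 17 lower), 15 in CRL-1999 minus Jurkat untreated and 2 in BE(2)-C minus CRL-1999, with 1 smooth muscle contractile gene. With arrays scaled to one median absolute deviation 1 was enriched in Jurkat serum, 2 in BE(2)-C, 22 in CRL-1999 and 1 in all 3 cell types, and 22 differed in BE(2)-C minus Jurkat untreated, 12 in CRL-1999 minus Jurkat untreated (5 higher, 7 lower) and 14 in BE(2)-C minus CRL-1999, with 3 smooth muscle contractile genes. The authors' series matrix values gave 10 enriched in CRL-1999, 7 in all 3 cell types, 1 differing in Jurkat serum minus Jurkat untreated, 32 in BE(2)-C minus Jurkat untreated, 16 in CRL-1999 minus Jurkat untreated, 2 in BE(2)-C minus CRL-1999 and 1 smooth muscle contractile gene.

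With dim probes left out 8 were enriched in CRL-1999 and 7 in all 3 cell types, and 22 differed in BE(2)-C minus Jurkat untreated and 11 in CRL-1999 minus Jurkat untreated. With at least 3 probes 7 were enriched in CRL-1999. The best neighbouring pair of probes gave 126 enriched in Jurkat serum, 109 in Jurkat untreated, 59 in BE(2)-C, 25 in CRL-1999 and 10 in all 3 cell types, 1 differing in CRL-1999 minus Jurkat untreated, and 11 immediate early, 6 actin cytoskeleton, 3 smooth muscle contractile, 2 T cell and 1 olfactory receptor genes. The median over probes gave 22 in Jurkat serum. The variance trend and robust fit gave 7 in BE(2)-C minus Jurkat untreated and 4 in CRL-1999 minus Jurkat untreated.

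Array weights gave 10 enriched in Jurkat serum, 100 in Jurkat untreated, 32 in BE(2)-C, 31 in CRL-1999 and 11 in all 3 cell types, and 413 differing in BE(2)-C minus Jurkat untreated, 92 in CRL-1999 minus Jurkat untreated and 713 in BE(2)-C minus CRL-1999, with 5 actin cytoskeleton, 5 smooth muscle contractile and 4 ribosomal protein genes. The replicate block gave 14 enriched in Jurkat serum, 30 in Jurkat untreated, 5 in BE(2)-C, 0 in CRL-1999 and 0 in all 3 cell types, 0 in BE(2)-C minus Jurkat untreated and 1 in CRL-1999 minus Jurkat untreated, with 0 actin cytoskeleton, 0 T cell and 1 ribosomal protein genes. The scan day as a random block gave 22 enriched in Jurkat serum, 15 in Jurkat untreated, 2 in BE(2)-C, 0 in CRL-1999 and 0 in all 3 cell types, 1 in BE(2)-C minus Jurkat untreated and 1 in CRL-1999 minus Jurkat untreated, with 2 immediate early, 0 actin cytoskeleton, 0 T cell and 1 ribosomal protein genes. The lower minimum fold gave 102 in Jurkat serum, 103 in Jurkat untreated, 17 in CRL-1999 and 9 in all 3 cell types, with 5 actin cytoskeleton, 4 smooth muscle contractile and 2 olfactory receptor genes. The higher minimum fold, 2, gave 7 in Jurkat serum, 20 in Jurkat untreated, 7 in BE(2)-C, 0 in CRL-1999 and 0 in all 3 cell types, with 0 actin cytoskeleton, 0 T cell and 1 ribosomal protein genes.

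The probe length correction gave 8 enriched in CRL-1999, 24 in BE(2)-C minus Jurkat untreated and 12 in CRL-1999 minus Jurkat untreated, and the replicate block with probe length correction 17 in Jurkat serum, 11 in BE(2)-C, 2 in all 3 cell types, 7 in BE(2)-C minus Jurkat untreated and 13 in CRL-1999 minus Jurkat untreated. Without the Jurkat serum group 94 were enriched in Jurkat untreated, 28 in BE(2)-C, 18 in CRL-1999 and 9 in all 3 cell types. In that fit 384 differed in BE(2)-C minus Jurkat untreated (198 higher, 186 lower), 37 in CRL-1999 minus Jurkat untreated and 449 in BE(2)-C minus CRL-1999. Of these calls 61, 25 and 12, in the same order, were enriched in either group compared. Without the CRL-1999 arrays of scan day 5 the counts were 0 in CRL-1999, 0 in all 3 cell types, 7 in BE(2)-C minus Jurkat untreated and 1 in CRL-1999 minus Jurkat untreated, and without those of scan day 6 they were 0, 0, 7 and 2. With only the 2 groups compared 292 differed in BE(2)-C minus Jurkat untreated, 2 in CRL-1999 minus Jurkat untreated and 643 in BE(2)-C minus CRL-1999. With Jurkat serum as the Jurkat comparator 15 differed in BE(2)-C minus Jurkat untreated (7 of the 11 calls among them) and 1 in CRL-1999 minus Jurkat untreated, and with the mean of both Jurkat groups as the comparator 21 and 11 differed in BE(2)-C and CRL-1999. Adjusted over the 71 enriched regions alone, 4 differed in Jurkat serum minus Jurkat untreated, 56 in BE(2)-C minus Jurkat untreated, 52 in CRL-1999 minus Jurkat untreated and 4 in BE(2)-C minus CRL-1999.

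With each replicate left out, the counts ranged from 21 to 80 in Jurkat serum, 12 to 75 in Jurkat untreated, 3 to 19 in BE(2)-C, 0 to 8 in CRL-1999 and 0 to 7 in all 3 cell types. They ranged from 0 to 86 in Jurkat serum minus Jurkat untreated, 1 to 22 in BE(2)-C minus Jurkat untreated, 1 to 14 in CRL-1999 minus Jurkat untreated and 0 to 0 in BE(2)-C minus CRL-1999. Lists ranged from 5 to 7 immediate early, 1 to 4 actin cytoskeleton, 1 to 2 ribosomal protein, 0 to 1 smooth muscle contractile and 0 to 2 T cell genes.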

Other observations

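The tests of the olfactory difference of BE(2)-C and CRL-1999 on probe length and dim probes were written before the result was seen, and all other tests here, the olfactory test in Jurkat with serum included, were chosen only after it.

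TAGLN and CALD1, smooth muscle genes, and MYH9, a non-muscle myosin gene, passed in CRL-1999 without the Jurkat serum group, at log2 1.73, 1.74 and 1.88 (adjusted p = 0.0373, 0.0171 and 0.0205). These are the higher of 2 regions of each gene, and the other regions lay at 0.08, 0.12 and 0.11 and did not pass. In that fit the first CALD1 region lay higher in CRL-1999 than in untreated Jurkat (1.60, adjusted p = 0.0197), and TAGLN lay lower in BE(2)-C than in CRL-1999 (-1.97, adjusted p = 0.0147). DUSP5 lay higher in BE(2)-C than in CRL-1999 (2.25, adjusted p = 0.0127) and than in untreated Jurkat (1.34, adjusted p = 0.0355). ACTA2 was enriched in untreated Jurkat (1.54, adjusted p = 0.0367) and lower in BE(2)-C (-1.69, adjusted p = 0.0117), as it was against CRL-1999 (-1.71, adjusted p = 0.0186). TAGLN, CALD1 and MYH9 were chosen after their values were seen, as was this fit.

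The serum replicates agreed little, with a median r of 0.150 across regions, and serum replicate 2 followed probe length (r 0.546 on array a and 0.623 on array b). Probe length is argued against as the whole cause, since the median r was 0.187 with the probe length correction (lowest other group 0.398). Dim probes are argued against likewise, since it was 0.132 without them (lowest other group 0.395). Different days need not bring such low agreement, since CRL-1999 arrays of different days had a lowest r of 0.386, above the highest of 0.309 between serum arrays. An effect of the serum days themselves stays open, because each serum replicate had a day of its own.

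The 285 olfactory receptor promoters, genes of odour receptors, had means of 0.52 in Jurkat with serum and 0.46 in BE(2)-C, 0.04 in untreated Jurkat and -0.25 in CRL-1999. With the probe length correction 66.4% of the mean in Jurkat with serum was gone (0.52 to 0.17), which fits a probe length trend there. For the difference of BE(2)-C and CRL-1999 probe length is argued against as the main cause, since 30.5% was gone. Without dim probes 111% of that difference was gone, with 119 promoters left, which leaves that cause open. With loess within arrays 90.7% was gone, which fits a trend of the ratio on probe brightness, though loess may also remove a real shift shared by probes of like brightness.

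The 71 enriched regions lay between divergent genes in 10 cases (14.1%), against 1441 of 16720 others (8.62%), with an odds ratio of 1.74 (0.792 to 3.43, Fisher's exact p = 0.132). The highest probe lay nearer the transcription start than the other probes of its region by a mean of -82.4 bp (SD 343, 71 regions, permutation p = 0.0473, adjusted p = 0.0947 over 2 hypotheses). Its median distance was 268 bp, and it lay upstream in 57 of 71, at EGR1 by -431 bp and at SRF by -41 bp. The share of upstream probes among the other probes was not counted, so 57 of 71 may reflect where probes were placed.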
